A study of Oryza sativa Indica Group with 2 samples.

How the data were processed

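RNA from rice seedlings was sequenced in 2 libraries, 1 of the wild type (WT) and 1 of the OsGRF7 overexpression line (GRF7OE). Per the labels' protocols, plants were grown in Wuhan in summer, total RNA (3 µg) was extracted with TRIzol and treated with DNase I, and libraries followed standard Illumina steps. Per the submitters' processing notes, Bowtie and Cuffdiff were used; their versions, and the genome build, are not given in the sources used here. Genes carry RAP and MSU identifiers, per the file headers.

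The authors deposited 1 table of 35677 genes. Its FPKM columns hold expression scaled to transcript length and library size, as the authors computed it. Its count columns hold a signal per gene, the authors' normalised read count, in which 1 read is worth 0.963 in GRF7OE and 0.954 in WT. Values below 10000 were whole multiples of that step, within 0.05, for 99.3% of genes above 0 in GRF7OE and 99.2% in WT. Dividing by the step gave about 17021467 reads in GRF7OE and 16824988 in WT, which set the precision of each ratio. The deposited p-value and FDR columns come from the authors' comparison of the 2 libraries. Their stated rule for a significant call is an FDR of at most 0.05 and an absolute log2 ratio of at least 1. The deposited log2 ratio equals the log2 ratio of the FPKM columns, within 0.001, for all 28656 genes above 0 in both libraries. It is -1 for the 5054 genes at 0 in both, and its sign goes against the FPKM values in 931 of the 1967 genes at 0 in 1 library. For that reason it was not used, and directions were taken from FPKM.

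The main measure was log2((GRF7OE FPKM + 1) / (WT FPKM + 1)), for the 23397 genes with a mean of at least 1 FPKM over both libraries, and genes at 2-fold or more on that scale were counted. The pseudocount of 1 understates the ratio of low genes, so folds of named genes are given as plain FPKM ratios. Each has a 95% exact (Clopper-Pearson) interval from its read counts. Intervals and floors cover counting error only. Where 1 library had 0 reads, a floor of 3 reads per library was set, and no fold is given when both libraries were at or under it.

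For each gene list, the median log2 ratio of members with a mean of at least 1 FPKM was set against 10000 random lists with the same number of genes in each of 20 expression bins (seed 1). Lists with under 3 such members got values only. Before the data were examined, 25 lists of 308 symbols, the 2-fold rule and most of the alternatives were fixed. Of the symbols 295 were measured, 4 had IDs not analysed here, and 9 were dropped because the table names their ID otherwise, as for several PIN genes. Where an ID has more than 1 entry, the entry with the higher mean was taken. Genes were named by a fixed rule. The rule takes OsGRF7, then the 10 genes with the largest and the 10 with the smallest log2 ratio among those with a status of OK. It adds up to 4 members per list with the largest absolute log2 ratio, and always CYP714B1, ARF12, GA20ox2 and SLR1. Symbols are used where the table pairs them with the ID, and IDs otherwise. A RefSeq gene table of the species could be linked to only 4 genes and was not used, so no coordinates are given.

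The counting and list steps were tested on simulated reads drawn for 23397 genes from these libraries' levels and depths, with 200 genes changed. For 3-fold changes 48 of 50 higher and 46 of 50 lower genes were called, and for 8-fold changes 50 of 50 and 45 of 50. A list of 12 genes shifted by 0.5 came out at percentile 100, and 4 of 100 unchanged lists fell outside the range of 95% of random lists. With 1 library per group, no test of the conditions was run. The alternatives tried were pseudocounts of 0.1 and 0.5, other filters on low values, scaling to a median ratio of 1 or to the same sum, other fold sizes and other thresholds on the authors' calls. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.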

Results

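Messenger RNA was sequenced from rice seedlings of the Indica group at the tillering stage, the stage at which side shoots form. One group was the wild type (WT, 1 library) and the other was a transgenic line that overexpresses OsGRF7 (GRF7OE, 1 library). OsGRF7 is a transcription factor of the growth-regulating factor family, whose members are targets of the microRNA miR396. The series asks which genes differ between the line and the wild type, in the setting of plant architecture. About 16824988 reads were assigned to genes in WT and about 17021467 in GRF7OE. Expression is given as the deposited FPKM, the read count scaled to transcript length and library size, with GRF7OE named first and WT after "against". With 1 library per group no difference has a replicate check, and no test of the conditions was possible. Brackets after a fold hold its 95% exact counting interval from the reads, which covers counting error only and not the difference between plants.

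OsGRF7 itself was far higher in the transgenic library, at 70.7 FPKM against 5.10 FPKM in WT. The ratio was 13.9-fold [11.9 to 16.2], from about 2522 reads against 180, and the log2 ratio with a pseudocount of 1 was 3.56. The library labelled as overexpressing OsGRF7 was thus the one with more of its transcript. In the authors' deposited table OsGRF7 has an FDR of 0, and that value compares these 2 libraries, not the conditions. The other growth-regulating factors showed no such difference. Of the 11 family members with a mean of at least 1 FPKM, OsGRF7 was the 1 that differed by 2-fold or more on this scale. GRF3 was at 14.7 FPKM in GRF7OE and 22.5 in WT, with a log2 ratio of -0.59. GRF2 and GRF12 were lowly expressed, on at most 32 reads per library, with log2 ratios of -0.41 and 0.58. The list's median was 0.11, at percentile 87.4 among 10000 random lists of the same size and expression. The percentile is the percentage of those random lists with a lower median, and it describes these libraries only. GRF-interacting factors, the transcriptional coactivators that bind GRF proteins, lay close to WT in all 3 members, none of them 2-fold apart. GIF1, GIF2 and GIF3 had log2 ratios of -0.17, 0.08 and -0.05, and the sign for GIF2 turned when both libraries were scaled to the same sum. Their median was -0.05, at percentile 42.6.

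Across the transcriptome, more genes were higher in GRF7OE than lower. Among 23397 genes with a mean of at least 1 FPKM, 758 were at least 2-fold higher and 293 at least 2-fold lower, which is 4.49% of these genes. The higher ones made up 72.1% of the 1051. Most genes were alike in both libraries, with 86.0% within 1.5-fold and a median log2 ratio of -0.01. A 4-fold difference was reached by 94 genes on the higher side and 25 on the lower side. In simulated libraries, counting noise alone put 41 of the 23197 genes simulated without change past 2-fold higher and 19 past 2-fold lower. The authors' deposited table calls 422 genes significant, 331 of them higher and 91 lower in GRF7OE. Its p-values compare the 2 libraries, not the conditions. Of the genes past 2-fold, 320 of the higher and 86 of the lower are among them. The number of genes past 2-fold moved with the settings. It was 1147 higher and 512 lower with a pseudocount of 0.1 in place of 1, and 481 and 165 at a mean of at least 5 FPKM. From the normalised count columns it was 1109 and 505.

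**Figure D1:**
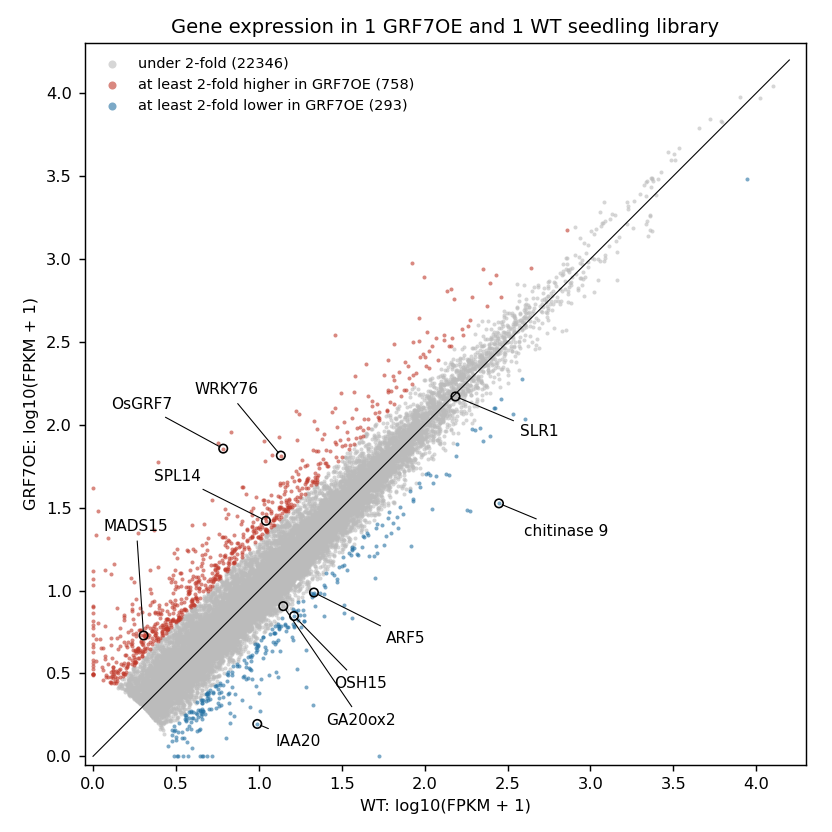
Each point is a gene with a mean of at least 1 FPKM; the x axis is log10(FPKM + 1) in the WT library, the y axis is log10(FPKM + 1) in the GRF7OE library, and the line marks equal values. Red points are the 758 genes at least 2-fold higher in GRF7OE and blue points the 293 at least 2-fold lower; OsGRF7 lies far above the line, SLR1 on it, and IAA20 and chitinase 9 far below it.

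Among the 10 genes with the largest log2 ratios, a fasciclin-like arabinogalactan protein (OS02G0308400), of a family of cell surface glycoproteins, was at 88.8 FPKM against 5.78, 15.4-fold higher [11.9 to 20.1]. Germin-like protein 3-2 (OS03G0651800), an extracellular protein of a family linked to defence, was at 21.3 FPKM against 0.859, 24.8-fold higher [11.8 to 62.6]. A protein with a von Willebrand factor type A domain (OS11G0687100) was at 76.8 FPKM against 4.68, 16.4-fold higher, and OS01G0537250, a gene described only as hypothetical, was at 349 FPKM against 28.0. Nearly silent in WT were OS03G0629800, with about 449 reads against 1, and OS07G0582800, with about 464 reads against 1. Their ratios were 448-fold [80.0 to 17744] and 491-fold [87.7 to 19445], with intervals this wide because WT had a single read. OS03G0115800 was 87.6-fold higher [37.3 to 271], and OS07G0511400 40.3-fold higher [24.6 to 71.0]. A pair of chloroplast-type genes, OS03G0659266 and OS11G0592350, also ranked among the 10 highest, but rested on 1 and 3 reads in GRF7OE and 0 in WT, too few for a fold.

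Among the 10 genes with the smallest log2 ratios, chitinase 9 (OS05G0399400), a pathogenesis-related enzyme that cleaves fungal chitin, was at 32.5 FPKM in GRF7OE and 280 in WT, 8.60-fold lower [7.77 to 9.54]. A cytochrome P450 described as an ent-kaurene oxidase (OS06G0569900), of the family that includes the gibberellin pathway enzyme, was 11.1-fold lower [8.54 to 14.7]. IAA20 (OS06G0166500), an Aux/IAA repressor of auxin signalling, was at 0.568 FPKM against 8.79, 15.5-fold lower [8.43 to 31.6]. A Bowman-Birk type trypsin inhibitor (OS01G0124401) was 6.08-fold lower [5.47 to 6.76], and a cysteine-rich repeat secretory protein (OS04G0659300) 6.43-fold lower [5.71 to 7.26]. A xyloglucan endotransglucosylase/hydrolase (OS06G0335975), an enzyme that remodels cell wall xyloglucan, had about 2 reads against 41, 19.5-fold lower [5.08 to 167]. It shares its MSU identifier with a neighbouring copy, OS06G0335900, so the division of reads between them is uncertain. OS04G0643800 was 10.6-fold lower [4.90 to 27.3]. OS02G0730050 was 6.10-fold lower [4.34 to 8.79], without being called significant in the authors' deposited table. The remaining genes among the 10 lowest, OS03G0333500 and OS05G0561400, had 1 and 3 reads in WT and 0 in GRF7OE, at or under the floor of 3 reads.

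Gibberellin synthesis and signalling genes, kept in 1 list, were modestly lower in GRF7OE. Of 12 measured members 8 had a mean of at least 1 FPKM, and all 8 had a ratio below 0, though none reached 2-fold. The ent-kaurene oxidase KO2 was at 16.2 FPKM against 30.9, 1.91-fold lower [1.73 to 2.12]. The gibberellin 20-oxidases, which make the precursors of active gibberellin, were lower as well. GA20ox1 was 1.93-fold lower [1.62 to 2.30], and GA20ox2, the gene of the semi-dwarf sd1 varieties, was at 7.05 FPKM against 13.0, 1.85-fold lower [1.45 to 2.37]. SLR1, the DELLA repressor of gibberellin signalling, was at 147 FPKM against 152, 1.04-fold lower [0.996 to 1.08], within counting error as deposited but at a log2 ratio of -0.14, outside it, with both libraries scaled to the same sum. The list's median log2 ratio of -0.49 lay below the medians of all 10000 random lists, of which 95% fell between -0.24 and 0.30. None of the 8 is called significant in the authors' deposited table. The rule for those calls also asks for an absolute log2 ratio of at least 1, which the members named here did not reach.

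Genes that inactivate or divert gibberellins differed both ways. Of 12 measured members 4 reached a mean of at least 1 FPKM. On the log2 scale with a pseudocount of 1, CYP714B1 alone was past 2-fold, at 1.03. It came to 0.97, just under 2-fold on that scale, with both libraries scaled to the same sum. The median of the 4 was 0.01, at percentile 57.7, and came to -0.06 under that scaling. CYP714B1, a gibberellin 13-oxidase, was 3.85-fold higher [1.23 to 16.0] at 2.21 FPKM against 0.573, but on about 15 reads against 4. CYP714B2 was 1.47-fold lower [1.23 to 1.77], and CYP714D1, the gene of the elongated uppermost internode mutant, was 1.72-fold higher [1.14 to 2.64]. A gibberellin 2-oxidase (OS01G0757200) was 1.93-fold lower [1.48 to 2.53].

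The list medians of auxin signalling genes were below the range of random lists, for both the response factors and their repressors. Counts past 2-fold here use the log2 scale with a pseudocount of 1. Of 25 Aux/IAA repressors with a mean of at least 1 FPKM, 22 had a ratio below 0 (21 with the median ratio scaled to 1), 4 were at least 2-fold lower and none 2-fold higher. Besides IAA20, these were IAA12 at 13.0 FPKM against 30.7, IAA18 at 1.84 against 5.45, and IAA16 at 1.19 against 3.61. The median of -0.38 was below all 10000 random lists. Among 23 auxin response factors, which bind auxin-regulated promoters, 19 had a ratio below 0, 1 was at least 2-fold lower and 1 higher, and the median of -0.23 was at percentile 0.13. ARF5 was at 8.73 FPKM against 20.5, 2.35-fold lower [2.15 to 2.57]. ARF12 went the other way, at 6.61 FPKM against 2.39, 2.77-fold higher [2.08 to 3.73]. ARF11 and ARF15 had log2 ratios of -0.68 and -0.58, and as a plain FPKM ratio ARF11 was 2.05-fold lower [1.62 to 2.61]. ARF5, IAA12 and IAA20 are called significant in the authors' deposited table, and ARF12 is not. In the list of auxin synthesis and transport genes 6 of 7 had a ratio below 0, none past 2-fold on that scale, with a median of -0.35 at percentile 1.95. The 4 members with the largest ratios were flavin monooxygenases of the YUCCA type, which make auxin. They were OS01G0224700 at -0.81, OS04G0128900 at -0.72, OS03G0162000 at -0.43 and OS01G0732700 at -0.35. As plain FPKM ratios OS01G0224700 was 2.59-fold lower [1.72 to 3.97] and OS04G0128900 2.22-fold lower [1.45 to 3.48]. With no filter on low values this median came to -0.16, inside the range of 95% of random lists.

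**Figure D2:**
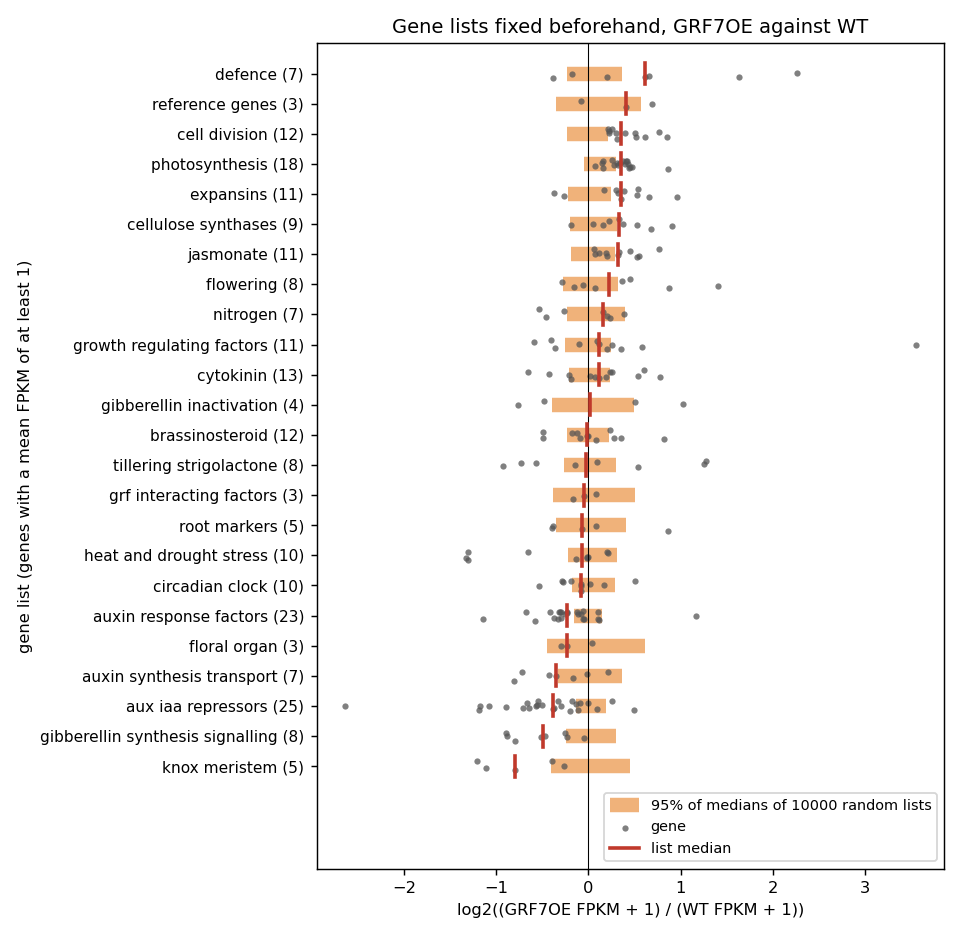
Each row is a gene list, with the number of members that had a mean of at least 1 FPKM; the x axis is log2((GRF7OE FPKM + 1) / (WT FPKM + 1)), points are genes, red bars list medians, and orange bands hold 95% of the medians of 10000 random lists of the same size and expression. KNOX, gibberellin synthesis and signalling, Aux/IAA, auxin response factor and auxin synthesis and transport lists lie below their bands, and 6 lists lie above them.

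KNOX homeobox genes, which keep shoot meristem cells undifferentiated, had a log2 ratio below 0 in all 5 members, with OSH3 within counting error. OSH15 was at 6.02 FPKM against 15.3, 2.54-fold lower with a log2 ratio of -1.22, and OSH71 2.97-fold lower [2.12 to 4.22]. OSH6 was 2.27-fold lower [1.53 to 3.41] and OSH3 1.56-fold lower [0.995 to 2.49]. On the log2 scale with a pseudocount of 1, 2 of the 5 were past 2-fold, OSH15 and OSH71. The median of -0.80 was at percentile 0.05, and OSH15 is called significant in the authors' deposited table.

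Genes tied to tillering differed in both directions, and both expressed genes tied to shoot angle were lower. SPL14, a transcription factor gene known for its part in panicle branching and tiller number, was 2.52-fold higher [2.19 to 2.92], with a log2 ratio of 1.25, and is called significant in the authors' deposited table. The MSU identifier of D53, the repressor of strigolactone signalling, has 2 entries. OS11G0104350, the one with the higher mean and a protein of 68 residues, was at 17.5 FPKM against 6.65, 2.63-fold higher [1.74 to 4.05]. The longer one of 435 residues, OS11G0104300, was at 15.8 FPKM against 7.90, with a log2 ratio of 0.92. The strigolactone receptor gene D14 was 1.67-fold lower [1.62 to 1.73] and the synthesis gene D17 2.48-fold lower [1.73 to 3.62]. Of the 8 genes 4 had a ratio above 0 and 4 below. On the log2 scale with a pseudocount of 1, at least 2-fold higher were 2 of them, and D17 was at -0.92. The median was -0.03, at percentile 47.7. For shoot angle 2 members were expressed, both at least 2-fold lower, and too few for a percentile. LPA1 was at 2.46 FPKM against 7.42, 3.02-fold lower [2.16 to 4.28]. OS11G0490600, for which the table gives no name, was 2.78-fold lower [2.37 to 3.28], with a log2 ratio of -1.38, and is called significant in the authors' deposited table.

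The fixed lists of cell division, expansin and cellulose synthase genes had medians modestly above 0. Cell wall families surveyed afterwards differed both ways. Callose synthases had a median of -0.41 in 15 genes, and glycine-rich cell wall structural proteins 0.03 in 22. Xyloglucan endotransglucosylases/hydrolases had 0.35 in 19 genes, endoglucanases 0.30 in 12 and polygalacturonases 0.22 in 19, all above the range of random lists. All 12 cell division genes had a ratio above 0, with a median of 0.36 at percentile 99.7, and none reached 2-fold on this scale. Of the B-type cyclins, which drive mitosis, CYCB2;2 had a log2 ratio of 0.85 and CYCB1;1 was 1.79-fold higher [1.49 to 2.15]. PCNA, the sliding clamp of DNA replication, was 1.55-fold higher [1.40 to 1.71] and the mitotic kinase CDKB2;1 1.45-fold [1.29 to 1.63]. Of 11 expansins, which loosen cell walls, 9 had a ratio above 0 and none reached 2-fold on the log2 scale, with a median of 0.35 at percentile 99.5. EXPA1 was 2.32-fold higher [1.58 to 3.46] and EXPA7 1.65-fold [1.39 to 1.98]. Cellulose synthases were above 0 in 8 of 9 members (7 with both libraries scaled to the same sum), none past 2-fold, with a median of 0.33 at percentile 98.2. CESA7 and CESA4, subunits of the secondary wall complex, were 1.90-fold [1.80 to 2.01] and 1.62-fold higher [1.53 to 1.71].

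Photosynthesis genes were higher in all 18 members, by under 2-fold, and in 17 with both libraries scaled to the same sum. Chlorophyll a-b binding protein 2 (OS01G0720500), a light-harvesting antenna protein, was at 2193 FPKM against 1204, and LHCB5 was 1.39-fold higher [1.37 to 1.42]. The median of 0.35 was at percentile 99.4.

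The short fixed lists of defence and jasmonate genes had medians above the range of random lists. These lists do not separate genes that promote a response from genes that repress it, so their medians do not show a raised response. Defence families surveyed afterwards differed both ways. Chitinases had a median of -0.49 in 17 genes and disease resistance proteins -0.17 in 70, both below the range. WRKY transcription factors as a family had 0.06 in 62 genes, inside it, and germin-like proteins 0.26 in 22, above it. WRKY76 was at 64.1 FPKM against 12.6, 5.10-fold higher [4.42 to 5.90]. OS09G0417800, also described as a WRKY factor, was 3.62-fold higher [2.72 to 4.89], and both are called significant in the authors' deposited table. A PR1-type pathogenesis-related gene (OS07G0129200) was 1.59-fold higher [1.39 to 1.82] and OS05G0322900, for which the table gives no name, 1.53-fold higher [1.47 to 1.60]. Of 7 defence genes 5 had a ratio above 0, 2 of them past 2-fold, with a median of 0.61 at percentile 99.9. All 11 jasmonate genes were above 0, 9 with both libraries scaled to the same sum, and none was past 2-fold, with a median of 0.32 at percentile 98.5. JAZ-type repressors of jasmonate signalling led them, OS03G0180800 at 1.76-fold higher [1.40 to 2.22] and OS03G0180900 at a log2 ratio of 0.55.

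Other fixed lists stayed inside the range of 95% of random lists, with single genes apart from the rest. Among 10 heat and drought genes the small heat shock genes HSP16.9A and HSP17.4 and the water stress-inducible Rab21 (OS11G0454300) were each at least 2-fold lower, with log2 ratios of -1.33, -1.31 and -1.31. HSP16.9A and HSP17.4 rested on about 6 and 9 reads in GRF7OE. That list's median was -0.07, at percentile 23.6. Flowering genes had a median of 0.22 at percentile 92.1, from 5 above 0 and 3 below, but of -0.06 at a mean of at least 5 FPKM. MADS15, a floral transition gene of the APETALA1 group, was at 4.36 FPKM against 1.02, 4.28-fold higher [2.82 to 6.70], and is called significant in the authors' deposited table. Protein HEADING DATE 3B (OS06G0157500), a florigen gene, was 2.30-fold higher [1.42 to 3.84]. Of 12 brassinosteroid genes 5 were above 0 and 7 below, with a median of -0.01 at percentile 55.8 that turned above 0 with the median ratio scaled to 1. DLT, a positive regulator of brassinosteroid responses, was 1.97-fold higher [1.64 to 2.37]. Cytokinin genes had a median of 0.11 at percentile 85.3, with 9 of 13 above 0, or 7 with both libraries scaled to the same sum. Nitrogen genes had a median of 0.16 at percentile 73.8, with 4 of 7 above 0. The cytokinin response regulator RR1 was 1.49-fold higher [1.29 to 1.72] and the glutamine synthetase GS1;2 1.46-fold lower [1.39 to 1.53]. Clock genes had a median of -0.08 at percentile 13.5, with 7 of 10 below 0 and none past 2-fold. Log2 ratios were -0.53 for LHY, 0.51 for PCL1 (OS01G0971800) and -0.29 for GI.

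Markers of other organs lay inside the range of random lists. Floral organ genes with a mean of at least 1 FPKM numbered 3 of 9, none of them past 2-fold, with a median of -0.23 at percentile 15.9. The 5 root markers had a median of -0.07 at percentile 34.5, with none past 2-fold on the log2 scale. The 3 with a mean of at least 5 FPKM had a median of -0.39, below the range. NRAMP5, a root manganese transporter, was 2.58-fold higher [1.74 to 3.90], while nicotianamine synthases 1 and 2 had log2 ratios of -0.40 and -0.39. Common reference genes differed among themselves. Actin-1 was 1.64-fold higher [1.49 to 1.80], a ubiquitin fusion gene (OS01G0328400) 1.33-fold higher [1.27 to 1.39], and elongation factor 1-alpha 1.06-fold lower [1.04 to 1.08]. Their median of 0.41 was at percentile 92.4.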

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

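The alternatives using the normalised count columns, a minimum of 30 reads and the PIN and AMT identifiers were chosen after seeing the data. No paired analysis was possible because each group has 1 library. OsGRF7 stayed inside its counting interval on the log2 scale with a pseudocount of 1 (3.34 to 3.78) under all 4 alternatives. That interval was kept when the pseudocount changed, and the log2 of the plain FPKM ratio, 3.79, lies just above it. The count of genes past 2-fold (758 higher, 293 lower) became 1147 and 512 with a pseudocount of 0.1, and 481 and 165 with a mean of at least 5 FPKM, which leaves fewer genes. It came to 2148 and 1121 at 1.5-fold and 94 and 25 at 4-fold, by construction. From the normalised count columns it was 1109 and 505. There the pseudocount of 1 stands for about 1 read and not 1 FPKM, so low genes are damped otherwise. How much of the change this makes was not tested. Scaling to the same sum gave 618 and 348, so the share of higher genes went from 72.1% to 64.0%. Restricting to status OK removed none of the counted genes. At an FDR of at most 0.01 the authors' calls numbered 189 higher and 46 lower instead of 331 and 91, a stricter threshold. Of 94 list medians recomputed with another pseudocount, filter or membership 92 kept their side of the range of random lists; scaling shifts those lists alike and is no check of it. The exceptions were auxin synthesis and transport with no filter (-0.16, inside the range), and root markers with a mean of at least 5 FPKM (-0.39 from 3 genes, below the range); the cause was not tested. Scaling to the same sum shifts log2 ratios by 0.09, and the sign turned for 2 named genes near 0, GIF2 (-0.01) and MADS16 (-0.05), among others in the lists. Of 440 recomputed ratios of the 110 named genes with a counting interval 403 stayed inside it, the interval again being that for a pseudocount of 1. For 4 named genes there is no such interval. Depth limits genes with few reads, where intervals span a wide range of folds.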

Other observations

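The survey of families, the tests of tissue share, of scaling, of depth and of annotation, the 3 patterns weighed and the genes named here were chosen after the values were seen. When all genes were grouped by the family named in their Swiss-Prot match, 205 families had at least 10 members with a mean of at least 1 FPKM. Medians above the range of 95% of random lists were found for 36 families and below it for 25, against 5.12 expected by chance on each side. Of the 24 fixed lists with a median 6 lay above and 5 below, against 1.2 expected in all. These percentiles treat genes as independent, which related genes need not be. The medians of 7 families lay above all 10000 random lists and those of 6 below all of them. Histones, the proteins that package new DNA, had a median log2 ratio of 0.77 in 43 genes, 12 of them at least 2-fold higher. A histone H2A.5 gene (OS03G0279200) was at 585 FPKM in GRF7OE and 193 in WT, although the division of reads between near-identical histone copies is uncertain. The 3-ketoacyl-CoA synthases, condensing enzymes of very long-chain fatty acids, had a median of 0.62 in 20 genes, and GDSL esterases/lipases 0.41 in 78 genes. Fasciclin-like arabinogalactan proteins had a median of 0.78 in 18 genes, dirigent proteins 0.85 in 15 and peroxidases 0.33 in 73. Past 2-fold, 6 dirigent proteins were higher and 2 lower, and 8 peroxidases higher and 2 lower. Of the 73 peroxidases 24 had a ratio below 0. Glutathione S-transferases had a median of 0.39 in 39 genes.

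On the lower side, chitinases had a median of -0.49 in 17 genes, 5 of them at least 2-fold lower and 1 at least 2-fold higher. All 13 genes named as trehalose-phosphate synthases by their Swiss-Prot match had a ratio below 0, with a median of -0.45. Callose synthases had a median of -0.41 in 15 genes and zinc transporters -0.42 in 14. The 331 pentatricopeptide repeat proteins, which process organelle RNA, had a small shift, with a median of -0.13. Of them 238 were below 0 and 93 above, and none was past 2-fold. Family medians, on either side, were not set against random lists matched on protein length, so length bias was not checked for them. Aux/IAA proteins, under the heading auxin-responsive protein, were the remaining family, with a median of -0.37 in 27 genes.

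The medians of the KNOX, Aux/IAA and auxin response factor lists all lay below the range of random lists. A smaller share of dividing shoot-apex tissue in the GRF7OE library could lower cell division genes as well. Their median was instead 0.36, above the range of random lists. Cell division genes also act in other dividing tissue, so this value cannot rule out a smaller shoot apex. Setting the median ratio to 1 left 0 of these 3 medians inside the range, but it shifts the random lists alike and so decides nothing about the authors' scaling. Auxin response factors were at percentile 1.36 among random lists matched on protein length instead of expression, against 0.13 among those matched on expression. Length bias may be part of their shift, but matching on expression was dropped as well, so the move cannot be credited to length alone. KNOX and Aux/IAA genes were at 0.02 and 0 when matched on length, so length bias does not account for all of the pattern. An effect of OsGRF7, a difference between individual plants and a different share of shoot-apex, meristem or stem tissue stay open. With 1 library per group they cannot be separated.

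Some genes were close to absent in WT alone. At least 30 reads in GRF7OE and at most 1 in WT were found for 17 genes, and the opposite for 0 genes. In 200 simulated pairs of libraries without change, drawn at the depth of each library, the highest such number was 0, so counting noise and deeper sequencing of the GRF7OE library are unlikely. A single stretch of chromosome that differs between the plants is argued against, as the genes lay on 9 chromosomes with 1 pair within 50 loci, against 2 at the upper edge of 95% of random sets, while differences at many single loci and an effect of OsGRF7 stay open. Of the 17 genes 14 had no Swiss-Prot match. Among these was OS06G0658400, at least 46.8-fold higher and described as a protein with a hAT dimerisation domain. Those with a match included a DOF-type transcription factor (OS02G0252400, about 104 reads against 0) and a hexokinase gene (OS07G0446800, about 94 reads against 1).

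Neighbouring genes tended to differ together: in the order of their RAP numbers, 120 pairs of direct neighbours were both at least 2-fold higher, against 24 in the median random set of like expression, and 27 pairs both 2-fold lower, against 3. Low counts do not account for the higher pairs, as 65 had at least 100 reads for each gene over both libraries, against 26 at the upper edge of 95% of random sets. Reads shared between copies of a gene may contribute, since 7 higher pairs had different annotation, the same number as in the median random set, while 20 had like annotation and 93 included a gene without a Swiss-Prot match, for which this was not tested. On chromosome 10, 12 of 15 genes from OS10G0148100 to OS10G0150800 were at least 2-fold higher, among them OS10G0150400 at 657 FPKM against 144; on chromosome 6, 9 of 10 genes from OS06G0121000 to OS06G0124300 were. Shared regulation of copies, overlapping transcripts and a differing stretch of chromosome stay open and were not tested.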
